A study of Mus musculus with 2 samples.

How the data were processed

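RNA was measured in 2 mouse embryonic fibroblast libraries, 1 with wild-type Usp16 (KS) and 1 with deleted Usp16 (UKS), both immortalized with SV40 T antigen. Per the labels' protocols, total RNA was extracted with TRIzol, checked on a Bioanalyzer and made into libraries with an Illumina TruSeq RNA kit. HISAT2, StringTie and the genome build GRCm38.p5 are named in the submitters' processing notes, without role or version. The program that gave the counts, the annotation release, the read length and whether counting used strand are not given in the sources used here. The files deposited by the authors hold estimated counts per gene (expected counts, not scaled to depth, with up to 2 decimals), 1 file per library and 51912 gene rows in each. Of the genes above 0, 23.1% had a count that was not whole in KS and 21.5% in UKS, so all were rounded to whole numbers before use. Without strand, reads of overlapping and antisense genes cannot be told apart, and reads shared between paralogs or pseudogenes may have been split, so values of such genes are uncertain.

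The totals were 26561637 counts in KS and 23205746 in UKS, at which 1 count equals 0.0379 and 0.0428 CPM and the floor of 3 counts equals 0.114 and 0.128 CPM. The 10 most abundant genes took 5.23% of the counts in KS and 6.33% in UKS. Groups were taken from the sample descriptions. TMM factors (0.994 for KS and 1.01 for UKS) were computed with edgeR 4.0.16 in R 4.3.3, and CPM were taken on the scaled totals. The main value was log2((UKS + 1)/(KS + 1)) with a pseudocount of 1 CPM over genes with a mean of at least 1 CPM, and a threshold of 2-fold was a size, not a test. A test between the groups was not made, because each has 1 library. Ratios of counts carry exact conditional binomial (Clopper-Pearson) 95% intervals and single counts exact Poisson intervals from scipy 1.17.1. Genes with no counts in 1 library are given as a bound against 3 counts in that library.

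The 40 gene lists, the rule for named genes and all alternatives not marked as added were fixed before the data were examined. A list of at least 5 measured members was described by its median and by the percentile of that median among 10000 random lists of the same size drawn from 20 bins of equal gene number by mean level, and it was counted as above or below when outside the central 95%. Genes of a random list were drawn independently, while members of a fixed list may vary together or share reads. The central 95% can then be too narrow for such a list, so a percentile describes a position and is not a p-value. Of 36 ranked lists 12 lay above, 10 below and 14 inside. Of the 12 above 8 stayed so with the trend removed, and of the 10 below 6 did. The rule named Usp16, the 15 genes with the highest and the 15 with the lowest ratio, the 10 highest and 10 lowest among genes with a mean of at least 50 CPM, up to 4 members per list with the largest absolute ratio, and the 2 most abundant members of lists for other cell types. Results for some genes that the rule also takes in, and a further engineered alteration shared by both lines, are not reported here. Predicted gene models were counted but not named. A symbol on several rows was not named, and 100 symbols were shared by 204 rows. In the files, 3 list symbols were not found.

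Coordinates, gene types, transcript length and GC content came from GENCODE M21 on GRCm38, in which 51633 of the 51912 gene identifiers were found. Each gene was given the length and GC content of its longest protein-coding transcript, or of its longest transcript if none was protein-coding. The build named in the notes is a patch release, which leaves chromosome coordinates as they are. The trend with length and GC content was a robust regression (Tukey's biweight, statsmodels 0.14.6) on cubic terms of log2 length (limited to 200 to 20000 nt) and of GC content (limited to 35 to 65%), fitted on genes in no fixed list and subtracted from the log2 ratio of the 12997 genes with both properties; 18 genes had none. This correction was added after the trend had been seen. It treats the whole trend as removable and would also remove a real difference that follows length or GC content. The transcript taken need not be the one expressed, so the trend subtracted from a gene can be too large or too small.

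The steps were tested on simulated data, a simulated UKS over KS comparison of 13009 genes at the real depths. Of genes set 2.5-fold apart 89.8% came out past 2-fold in the right direction, of those 4-fold and 8-fold apart 100%, and of those 1.5-fold apart 0%. None of the 12811 unchanged genes passed 2-fold by counting error, which says nothing of variation between cultures. A list shift of 0.5 planted under a linear trend, with counting error alone, was recovered as 0.487. Spearman's correlation of the simulated ratio with GC content was 0.933 before and −0.075 after correction, against 0.52 before correction in the data. The simulated trend was thus simpler and cleaner than the real one, so the recovery does not show how well the correction works on these libraries. Alternatives were CPM on library totals, median-of-ratios scaling, pseudocounts of 0.1 and 5 CPM, no level minimum and a minimum of 5 CPM, protein-coding genes alone, thresholds of 1.5-fold and 4-fold, the trend removed, and genes on X and Y left out. Lists were ranked against 2000 random lists under each alternative. An alternative with a second unit was not run, because the files used here hold 1 unit. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 was used throughout.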

Results

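The data were 2 RNA-seq libraries from mouse embryonic fibroblasts (MEFs), connective tissue cells cultured from embryos, here on a C57BL/6 background. Both lines had been immortalized with SV40 T antigen, a viral protein that inactivates p53 and the RB proteins. Both had received adenovirus carrying Cre recombinase, which deleted Usp16 in the line where that gene was floxed. The line with wild-type Usp16 is called KS and the line with deleted Usp16 is called UKS, and each gave 1 library. The comparison asks which transcripts differ between these fibroblasts with and without Usp16. The deposited values were estimated read counts per gene, which summed to 26561637 in KS and 23205746 in UKS, with 20218 and 19140 genes above 0. Levels were expressed as TMM-scaled CPM (counts scaled to a common library total) and compared as log2((UKS + 1)/(KS + 1)) over the 13015 genes with a mean of at least 1 CPM, a scale that understates the difference of low genes, while folds are ratios of CPM. Genes past 2-fold were counted on the log2 scale, so a gene with a CPM fold above 2 can go uncounted. With 1 library per group the differences have no replicate check, so no p-values are given and each value describes these 2 libraries. Intervals in brackets are exact 95% intervals of the ratio of counts and cover counting error only.

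Usp16, a deubiquitinase that removes ubiquitin from histone H2A, was lower in the UKS library. The gene (ENSMUSG00000025616; GRCm38 chromosome 16, 87454703 to 87483517, plus strand) had 1195 counts (45.3 CPM) in KS and 459 counts (19.7 CPM) in UKS, 2.30-fold lower [2.07 to 2.57] and a log2 ratio of −1.16. Its 38 measured neighbours within 5 Mb had a median log2 ratio of 0.02, but they were not matched to it in length or GC content. The 200 genes nearest to Usp16 in transcript length and GC content had a median log2 ratio of −0.26. Of these 200 genes 7% had a lower ratio than Usp16, so its ratio was low but not outside those of similar transcripts. Counts per gene do not show which exons the remaining UKS reads came from, so they bear on the deletion only in part. Ratios across the transcriptome followed transcript length and GC content, and with that trend removed the log2 ratio of Usp16 was −0.88, within 2-fold.

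Across the transcriptome 756 genes (5.81%) were at least 2-fold higher in UKS, 1396 (10.7%) were at least 2-fold lower and 10863 (83.5%) lay within 2-fold. After Xist, and leaving out predicted gene models, the genes that stood highest in UKS were Lcn2, C3, Col23a1, Saa3 and Cxcl1. Lcn2, which encodes the siderophore-binding protein lipocalin 2 (chromosome 2, 32384633 to 32388252), had 4 counts in KS and 4619 in UKS, 1306-fold higher [510 to 4794]. The complement component C3 (chromosome 17, 57203970 to 57228136) was 154-fold higher [114 to 213], the neutrophil chemokine Cxcl1 (chromosome 5, 90891241 to 90893115) 110-fold higher [85.8 to 143] and the collagen Col23a1 (chromosome 11, 51289920 to 51583918) 181-fold higher [124 to 275]. The serum amyloid gene Saa3 (4 and 2166 counts), the inducible nitric oxide synthase Nos2 (1 and 1168 counts, a ratio of 1321 [237 to 52206]), the transcription factor Sim2 (3 and 626 counts, 236 [80.4 to 1147]) and the amino acid transporter Slc7a8 (3 and 401 counts, 151 [51.3 to 736]) were close to undetected in KS. The protease inhibitor Slpi had no counts in KS and 535 in UKS, at least 202-fold higher against a floor of 3 counts. Ceruloplasmin (Cp) was 22.3-fold higher, the matrix protease Mmp3 22.9-fold, the chemokine Cxcl5 37.1-fold and the metalloreductase Steap4 74.8-fold. The MHC class I-like gene H2-T10, annotated as a polymorphic pseudogene, was 40.9-fold higher, a value that reads shared with related H2 genes could alter. Among abundant genes (mean of at least 50 CPM) the prostaglandin E synthase Ptges stood at 52.3 CPM in KS and 586 CPM in UKS, and proenkephalin (Penk) and decorin (Dcn) were 13.0-fold and 10.3-fold higher.

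After 4 Y-linked genes, the genes that stood lowest in UKS were Postn, Dkk2 and Agtr2. Periostin (Postn; chromosome 3, 54361109 to 54391037), a matrix protein of fibroblasts, had 231 CPM in KS and 6.25 CPM in UKS, 36.9-fold lower [31.3 to 43.8]. The WNT antagonist Dkk2 (chromosome 3, 132085292 to 132180304) was 37.9-fold lower [30.5 to 47.7], the X-linked angiotensin receptor Agtr2 22.6-fold, the transcription factor Ebf2 24.5-fold and the growth factor Igf2 12.3-fold. The X-linked Dgkk (117-fold), Clca3a1 (26.7-fold), the protease-activated receptor F2rl1 (24.4-fold), AW551984 (20.6-fold) and the transcription factors Bnc1 and Alx4 (each 16.0-fold) were also among the lowest. Abundant genes with lower levels in UKS further included the protein kinase Rock2 (9.50-fold), the caveola protein gene Sdpr (8.24-fold), Phip (8.19-fold), the matrix protein Efemp1 (7.98-fold), Medag (7.59-fold) and the guidance ligand Slit3 (7.17-fold). Xist and the Y-linked genes are described with the sex-linked genes. Each of these highest and lowest genes kept a difference of at least 2-fold when the trend with length and GC content was removed.

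**Figure D1:**
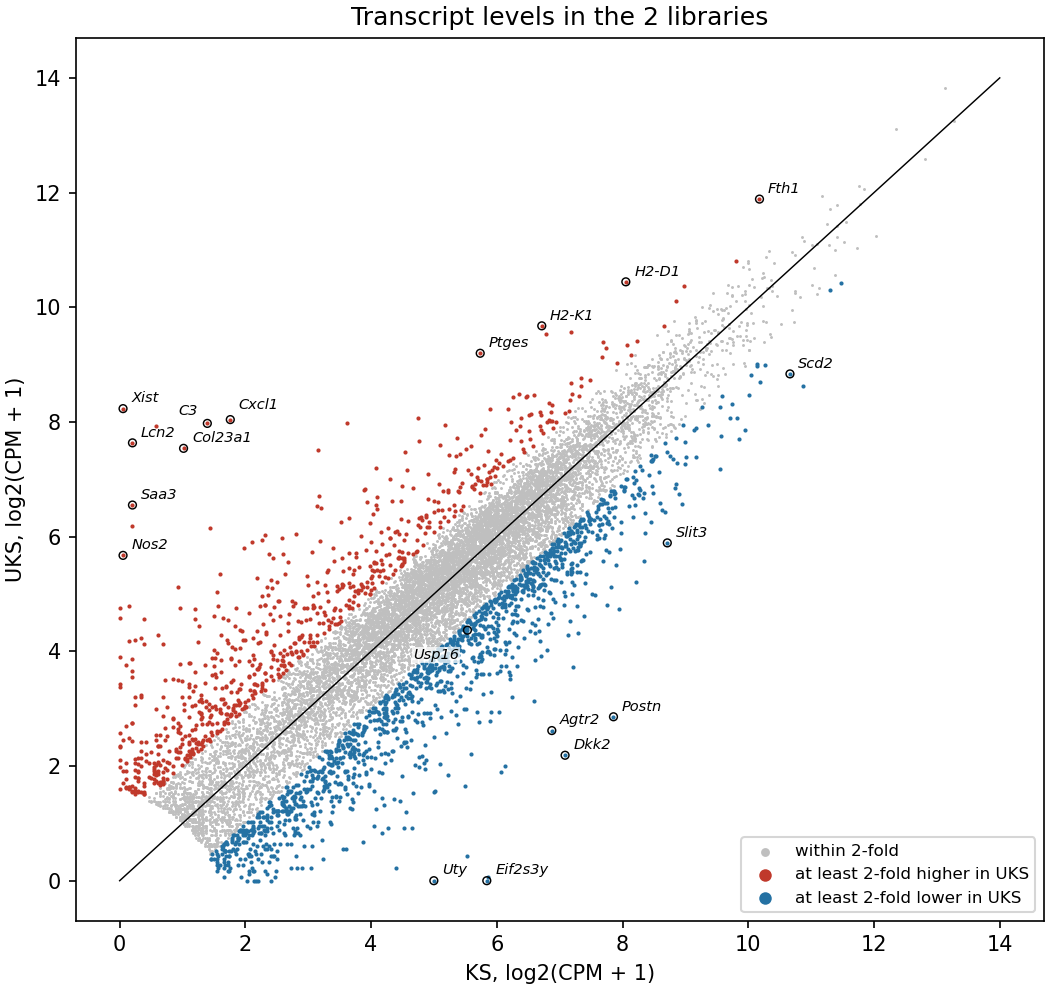
Level of each of 13015 genes in the KS library (x axis) and the UKS library (y axis), both as log2(CPM + 1), with 1 library on each axis and the line of equal levels. The 756 genes at least 2-fold higher in UKS and the 1396 at least 2-fold lower are coloured, with Lcn2, C3 and Cxcl1 far above the line and Postn and Dkk2 far below it.

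Short and GC-rich transcripts tended to be higher in UKS, and long and AT-rich transcripts lower. In the tenth of genes with the lowest GC content (median 39.8%) the median log2 ratio was −0.81, and in the tenth with the highest (59.9%) it was 0.40. In the tenth with the shortest transcripts (median 956 nt) it was 0.38, and in the tenth with the longest (8219 nt) it was −0.65. Across 12997 genes, which are not independent replicates, Spearman's correlation of the ratio was −0.40 with length and 0.52 with GC content. With the trend removed, 719 genes were at least 2-fold higher and 643 at least 2-fold lower, so the higher genes made up 52.8% of those past 2-fold in place of 35.1%. Of the 756 higher genes 551 stayed past 2-fold, and of the 1396 lower genes 547 did. Both values are given for each gene list whose standing this altered. Among the list members named below, Eif2ak2, Ghr, Cish, Cdkn2c, Cdkn2d, Pola1, Rrm2b, Bcl2, Ankrd37, Cebpb, Hmox1, Ddr2, Cebpa, Dsp and Chrna1 were past 2-fold as counted but within 2-fold with the trend removed. Further members that fell within 2-fold in the same way, such as Xiap and Kcnq1ot1, are described with their lists.

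**Figure D2:**
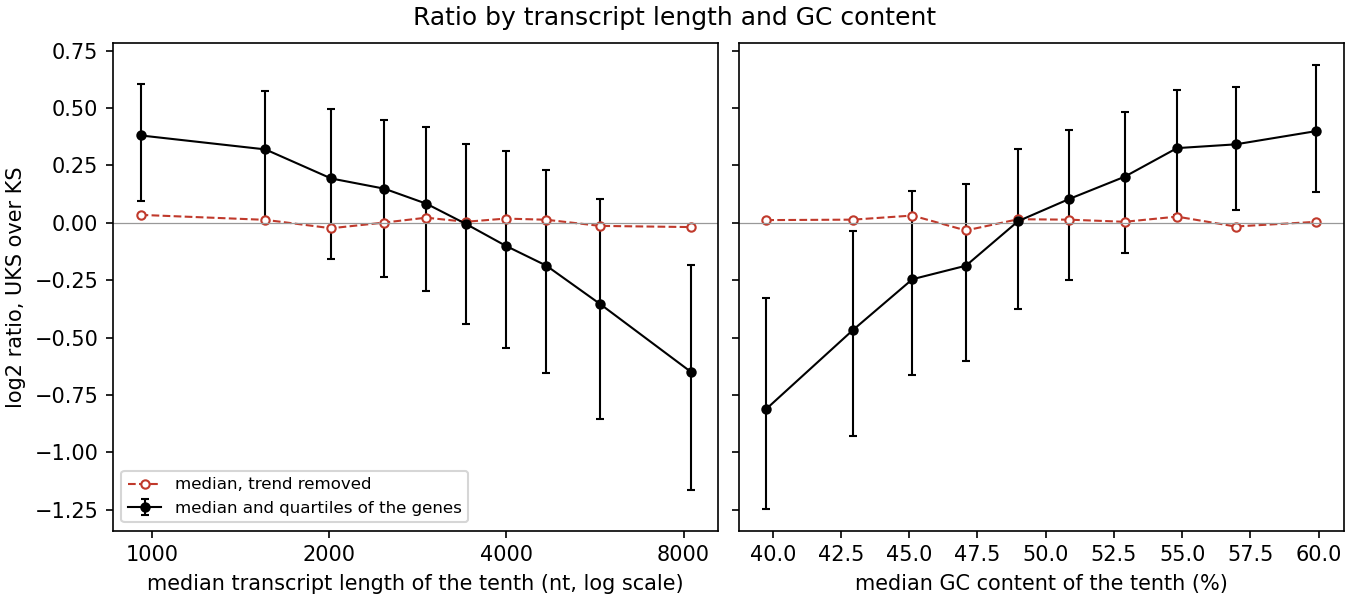
Median log2 ratio of UKS over KS (y axis) in 10 groups of equal gene number by transcript length in nt (left, log axis) and GC content in % (right), with bars from the lower to the upper quartile of the genes. The median runs from 0.38 to −0.65 with length and from −0.81 to 0.40 with GC content, and the open points with the trend removed lie near 0.

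Inflammatory transcripts formed the fixed list with the highest median. Of 32 measured NF-kB inflammatory genes, targets of the transcription factor NF-kB and members of its own pathway, 22 were at least 2-fold higher in UKS, 1 at least 2-fold lower and 9 between, with a median log2 ratio of 1.66. This median stood at percentile 100 of 10000 random lists matched on level, and it was 1.64 at percentile 100 with the trend removed. The list holds Lcn2, C3, Saa3 and Cxcl1 given above. Its lower member was the chemokine Cxcl12 (19820 counts in KS and 3359 in UKS, log2 −2.38), which was named after its value was seen.

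Transcripts of MHC class I antigen presentation were also higher in UKS. Of 19 measured members 14 were at least 2-fold higher and none at least 2-fold lower, with a median of 1.26 (percentile 100; 0.88, percentile 100, with the trend removed, when 7 were at least 2-fold higher). The classical class I heavy chain genes H2-K1 (chromosome 17, 33996017 to 34000347) and H2-D1 were 7.85-fold [7.55 to 8.18] and 5.26-fold [5.13 to 5.40] higher, reaching 817 and 1392 CPM, and H2-Q6 and H2-Q4 were 6.84-fold and 5.20-fold higher. The H2 genes are similar in sequence, so reads shared between them make the value of each one uncertain. Of 52 interferon-stimulated genes 13 were at least 2-fold higher and 1 lower, with a median of 0.43 (percentile 100). Ifitm1 (11.4-fold), the nucleic acid sensor Zbp1 (5.87-fold) and the oligoadenylate synthetases Oas1g (3.32-fold) and Oas1a (2.87-fold), which are similar in sequence, differed most, and the lower member was the kinase Eif2ak2 (log2 −1.07), named after its value was seen. The fixed list for the JAK-STAT pathway, which carries cytokine signals, was not limited to signalling components. Of its 40 measured members 4 were at least 2-fold higher and 3 lower, with a median of 0.21. This median lay inside the central 95% of random lists (percentile 94.3). Bcl3 (5.59-fold), Stat5a (2.85-fold) and the feedback inhibitor Cish (2.54-fold) were higher and the growth hormone receptor Ghr was 2.37-fold lower. With the trend removed the median of this list was 0.22, at percentile 99.8, and 3 members were higher and none lower.

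Genes downstream of RAS and ERK did not share one direction. Of 29 ERK output genes 5 were at least 2-fold higher in UKS and 1 lower, with a median of −0.23 (percentile 3.59) and a mean of 0.23, and with the trend removed 6 were higher and 3 lower. The cytokine Lif (9.09-fold), Ier3 (6.96-fold) and the EGF receptor ligands Areg (5.06-fold) and Ereg (4.05-fold) were higher, and the lower member was the feedback inhibitor Spry2 (log2 −1.15), named after its value was seen. Of 25 immediate-early genes 5 were at least 2-fold higher and none lower, among them Egr2 (5.67-fold), Junb (4.22-fold), Egr3 (3.96-fold) and Dusp2 (9.55-fold from 9 and 76 counts). The immediate-early median of 0.33 (percentile 97.9) was −0.03 (percentile 32.4) with the trend removed, when 4 were higher and 1 lower. Of 45 RAS pathway components 1 was at least 2-fold higher and 9 lower, with a median of −0.20 (percentile 2.45), against 0.00 (percentile 44.3) with the trend removed, when 1 was higher and 4 lower. The call was at the edge, since a redraw of the random lists with no other change put the median at percentile 2.78, inside the central 95%. Rgl1 (3.45-fold), the GTPase activator Rasa1 (3.21-fold) and the receptor Met (3.28-fold) were lower and the kinase Map3k5 was 3.41-fold higher.

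Replication genes were slightly higher in UKS and a part of the mitotic genes lower. Of 50 G1/S and replication genes 40 had a ratio above 0 but none was past 2-fold upward on the log2 scale. The median was 0.36 (percentile 99.97), and 0.30 with the trend removed. The GINS subunit Gins3 (2.09-fold as a ratio of CPM, log2 0.9998), the single-strand binding protein Rpa2 (1.86-fold) and the licensing factor Cdt1 (1.73-fold) were higher. The DNA polymerase subunit Pola1 was 2.56-fold lower. Of 56 G2/M and mitotic genes 13 were at least 2-fold lower and none at least 2-fold higher, led by the long transcripts of the centromere proteins Cenpf (7.37-fold) and Cenpe (5.92-fold), of Kif20b (5.60-fold) and of the proliferation marker Mki67 (4.50-fold). The G2/M median of −0.15 lay inside the central 95% of random lists (percentile 3.83), and with the trend removed 7 members were at least 2-fold lower, the 4 named ones among them. Of 8 CDK inhibitors Cdkn2c (2.45-fold) and Cdkn2d (2.05-fold) were at least 2-fold higher, Cdkn1a was 1.93-fold higher and Cdkn1c was 1.72-fold lower, with a median of 0.58 (percentile 99.6) that was 0.26 (percentile 94.5) with the trend removed, when none was higher and 1 was lower. Of 38 p53 targets 3 were higher, the death receptor Fas (5.33-fold), Gdf15 (4.78-fold) and Dcxr (3.37-fold), and 3 lower, Rrm2b among them (2.77-fold), with a median of 0.10 (percentile 71.3). With the trend removed 3 p53 targets were higher and 1 lower. Of 37 apoptosis regulators 3 were higher and 3 lower as counted, and 5 higher and none lower with the trend removed, with a median of 0.15 (percentile 82.2) as counted. The caspase Casp4 was 3.61-fold higher and the inhibitors Xiap and Bcl2 were 2.36-fold and 2.47-fold lower. The Xiap log2 ratio was −1.22 as counted and 0.05 with the trend removed. Of 40 DNA damage repair genes 6 were lower and none higher, including the kinases Prkdc (4.79-fold), Atr (4.22-fold) and Atm (3.61-fold) and the recombination factor Brca2 (4.40-fold), with a median of −0.39 (percentile 0.04) that was −0.11 (percentile 5.44) with the trend removed, when none was past 2-fold.

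Genes that mark fibroblasts and their contractile form were lower in UKS. Of 24 fibroblast identity genes 9 were at least 2-fold lower and 1 higher, with a median of −0.61 (percentile 0.02; −0.28, percentile 0.27, with the trend removed, when 6 were lower and 1 higher). The surface marker Thy1 (4.71-fold), the collagen receptor Ddr2 (3.33-fold) and the hyaluronan receptor Cd44 (3.15-fold) were lower and the transcription factor Snai1 was 4.70-fold higher. Of 29 TGF-beta and SRF/YAP contractile genes 7 were lower and 2 higher, with a median of −0.53 (percentile 0.01; −0.56 with the trend removed). Smooth muscle actin Acta2 (4.64-fold, 351 and 75.7 CPM), Actg2 (5.33-fold) and Ankrd1 (4.67-fold) were lower and the TGF-beta binding protein Ltbp2 was 6.81-fold higher. Extracellular matrix genes were divided, with 10 of 58 higher and 13 lower and a median of −0.10 (percentile 5.30), Mmp3, Dcn and Col15a1 (14.8-fold) on the higher side and Postn on the lower.

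Markers of other cell types were measured to describe what else the cultures could hold. Of 8 measured cartilage and bone markers 3 were at least 2-fold higher in UKS, with a median of 0.98 (percentile 100). The osteoblast factor Sp7 (16 and 192 counts) was 13.6-fold higher, the hypertrophic cartilage collagen Col10a1 (6 and 64 counts) 12.1-fold and Sox9 2.09-fold. Col11a2 was 3.53-fold higher as a ratio of CPM but stood at 0.99 on the log2 scale, so it was not counted. Among the most abundant members osteopontin (Spp1) was 1.70-fold higher and Runx2 1.69-fold lower. Adipocyte markers went both ways (7 measured, 2 higher and 2 lower, median 0.37, percentile 89.2), with the fatty acid binding protein Fabp4 11.0-fold and Cebpa 2.90-fold higher, lipoprotein lipase (Lpl) 17.5-fold and Plin4 2.54-fold lower, and the abundant Dlk1 1.82-fold higher. Of 12 neural and glial markers Gap43 (5.14-fold), Elavl4 (105 and 3 counts, a ratio of 31.0 [10.3 to 153]) and Mbp (4.14-fold) were lower, Stmn2 was 5.83-fold higher and the abundant Nes 1.29-fold higher, with a median of −0.28 (percentile 14.1). The 5 endothelial markers had a median of 0.33 (percentile 81.7), with Flt1 2.93-fold and Egfl7 1.73-fold higher, Eng within 0.01 of a log2 ratio of 0, and Kdr (38 and 19 counts) and Vwf (26 and 35 counts) with intervals that included equal levels. Few members were measured of the epithelial list (Dsp, Krt18 and Krt19, all lower, median −1.16), the blood cell list (Cd14 3.32-fold and Coro1a 2.78-fold higher, Cd68 1.21-fold lower, median 0.89) and the skeletal muscle list (Chrna1 4.13-fold lower, Myl4 1.35-fold higher with an interval that included equal levels, median −0.38). Of the germline list only Brdt was measured, with 71 and 76 counts.

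Hox genes had the lowest median of the ranked lists other than the sex-linked one. Of 30 measured Hox genes, which record position along the body axis, 12 were at least 2-fold lower in UKS and 2 higher, with a median of −0.90 (percentile 0), and −1.17 (percentile 0) with the trend removed, when 16 were lower and none higher. The Hoxc cluster on chromosome 15 held the largest differences, with Hoxc8 (102990607 to 102994111) 13.0-fold, Hoxc9 11.6-fold, Hoxc6 7.20-fold and Hoxc5 6.56-fold lower. The annotated Hoxc5 span contains Hoxc6, Hoxc8 and Hoxc9, so these counts may share reads. Developmental transcription factors were split, with 17 of 61 higher and 16 lower, a median of −0.05 (percentile 22.6) and a mean of 0.04. Zic1 (12.4-fold) and Irx3 (8.47-fold) were higher, and Ebf2 and Alx4 were lower as given above. WNT signalling genes showed large differences in both senses, with 7 of 34 higher and 9 lower and a median of −0.11 (percentile 18.9), which was −0.19 (percentile 2.03) with the trend removed, when 7 were higher and 6 lower. The ligand Wnt10a (8 and 386 counts) was 54.6-fold higher and the WNT-inactivating enzyme Notum 35.1-fold higher, while Dkk2 and the WNT inhibitor Sfrp2 (14.1-fold) were lower. Imprinting means expression from 1 parental copy, which was not measured in these cells. Of 27 measured members of the imprinted list 9 were lower and 1 higher, with a median of −0.54 (percentile 0.12). With the trend removed the median was −0.24 (percentile 1.16), when 6 were lower and 4 higher. The neighbours Igf2 and H19 were 12.3-fold and 4.28-fold lower, and Dcn, also a member of the matrix list, was the higher member as counted. The antisense transcript Kcnq1ot1 was 5.41-fold lower as counted, but its log2 ratio of −2.07 was −0.24 with the trend removed.

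**Figure D3:**
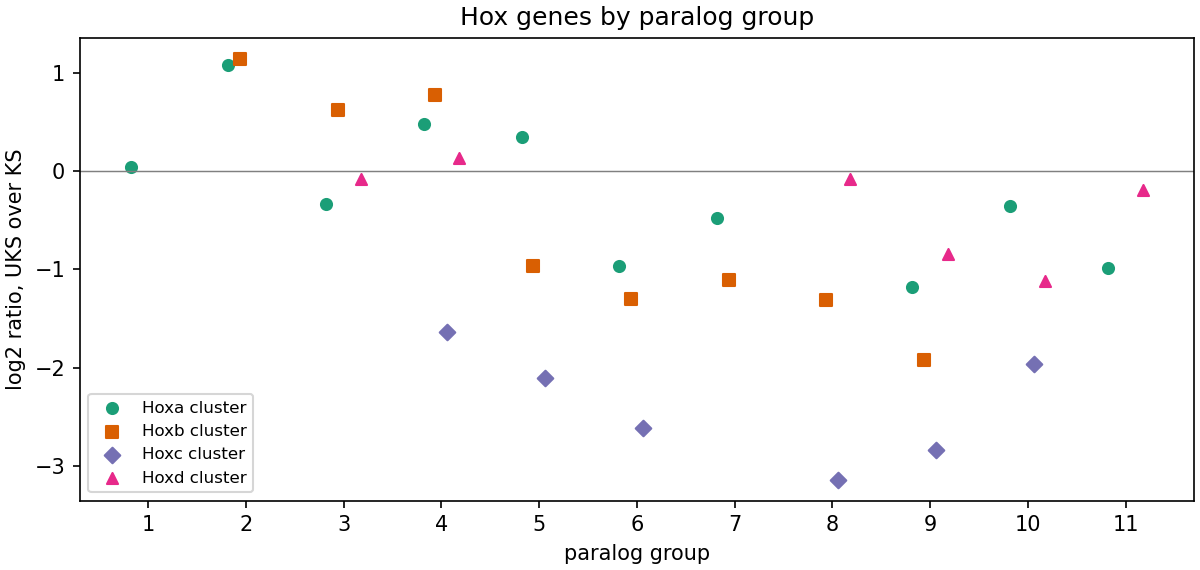
Log2 ratio of UKS over KS (y axis) of the 30 measured Hox genes by paralog group (x axis, from 1 at the head end of the body axis), 1 point per gene, coloured by cluster. All 6 measured Hoxc genes lie below 0, with Hoxc8 lowest at −3.14.

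Lipid synthesis was the metabolic group with the lowest median. Of 34 sterol and fatty acid synthesis genes 13 were at least 2-fold lower in UKS and none at least 2-fold higher, 32 had a ratio below 0, and the median was −0.84 (percentile 0; −0.87 with the trend removed). The fatty acid desaturases Scd2 (chromosome 19, 44293674 to 44306864; 1620 and 457 CPM) and Scd1 were 3.55-fold [3.47 to 3.62] and 4.02-fold [3.85 to 4.19] lower, and the elongase Elovl6 was 4.59-fold lower. Oxidative stress genes controlled by NRF2 were higher, 7 of 26 by at least 2-fold and none lower, with a median of 0.60 (percentile 100; 0.45 with the trend removed). The quinone reductase Nqo1 was 7.67-fold, Cbr3 4.69-fold, heme oxygenase Hmox1 2.43-fold and ferritin heavy chain Fth1 3.27-fold higher, the last reaching 3784 CPM.

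Of 37 integrated stress response genes, 3 were at least 2-fold higher and 7 lower, with Stc2 (4.02-fold), the amino acid transporter Slc7a5 (2.90-fold) and Chac1 (2.85-fold) lower and Cebpb 2.34-fold higher. The median of this list was −0.16 (percentile 4.94), and −0.32 (percentile 0) with the trend removed, when 1 was higher and 12 lower. Of 37 glycolysis and hypoxia genes 1 was higher, Ankrd37 (2.92-fold), and 2 were lower, Adm (5.62-fold) and Ndrg1 (2.22-fold), while Egln3 was 1.80-fold lower; the median of 0.34 (percentile 99.6) was 0.09 (percentile 86.6) with the trend removed, when none was higher and 3 were lower. Cytosolic ribosomal proteins were higher by a small and even amount, 78 of 81 above 0 and none past 2-fold, with a median of 0.46 (percentile 100) that was 0.12 (percentile 99.8) with the trend removed. Rpl37a (1.89-fold), Rps29 (1.78-fold), Rps27 (1.78-fold) and Rpl13a (1.75-fold) differed most, though ribosomal protein genes have many processed pseudogenes that could take up reads. Ribosome biogenesis factors had a median of −0.11 (percentile 9.88), which was −0.26 (percentile 0.04) with the trend removed, and 3 of 43 were at least 2-fold lower, nucleolin (Ncl, 2.22-fold), Utp20 (2.09-fold) and Gnl3 (2.03-fold), with Dkc1 1.93-fold lower. None of the 43 was past 2-fold with the trend removed. For Ncl this rests on its longest annotated protein-coding transcript (8202 nt), which need not be the one expressed. Nuclear genes of oxidative phosphorylation were above 0 in 59 of 60 cases, none past 2-fold, with a median of 0.46 (percentile 100; 0.13, percentile 97.7, with the trend removed), led by Ndufa2 (1.83-fold), Atp5e (1.82-fold), Ndufa5 (1.80-fold) and Ndufb9 (1.71-fold). The 13 protein-coding mitochondrial genome transcripts had a median of −0.50 (percentile 0.63), with mt-Nd2 (2.18-fold) and mt-Cytb (2.07-fold) at least 2-fold lower and mt-Nd4 and mt-Atp8 each 1.98-fold lower, and a median of 0.01 (percentile 52.9) over a range from −0.56 to 1.10 with the trend removed. The mitochondrial chromosome took 1.72% of the counts in KS and 1.21% in UKS.

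Chromatin genes related to Usp16 in function had medians below 0 as counted. Of 13 measured H2A deubiquitinases and their partners 2 were at least 2-fold lower, Asxl2 (2.65-fold) and Mysm1 (2.56-fold). Asxl3 was 2.24-fold lower as a ratio of CPM but stood at −0.90 on the log2 scale used for counting, and Brcc3 was 1.90-fold lower. The median of −0.68 (percentile 0.18) was −0.02 (percentile 42.6) with the trend removed, when none was past 2-fold and the log2 ratios of Asxl3 (0.02) and Brcc3 (0.28) lay above 0. Of 36 Polycomb repressive complex members, which write and bind the histone marks that include ubiquitinated H2A, 4 were at least 2-fold lower and none higher, Mga (3.32-fold), Phc3 (2.48-fold), Scml2 (3.36-fold) and Pcgf5 (2.12-fold), and the median of −0.16 lay inside the central 95% (percentile 6.52). None of these 4 was past 2-fold with the trend removed. Of 61 replication-dependent histone genes 8 were measured, with Hist1h4i 3.62-fold, Hist1h2bc 1.84-fold, Hist3h2a 1.86-fold and Hist1h1c 1.77-fold higher. Their median of 0.60 (percentile 98.7) was 0.09 (percentile 67.9) with the trend removed, and histone copies are similar in sequence, so each value is uncertain.

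The sex-linked list divided the libraries completely. Xist, the RNA that coats the inactive X chromosome (X, 103460366 to 103483254), had 1 count in KS and 6998 in UKS, a ratio of 7912 [1420 to 312567]. The Y-linked genes Eif2s3y (Y, 1010543 to 1028847) and Uty had 1486 and 817 counts in KS and none in UKS, at least 438-fold and 241-fold lower. Ddx3y had 1511 counts and 1 count, a ratio of 1336 [239 to 52819], and Kdm5d 1195 and 8, 132-fold lower [66.8 to 307]. The median of the 5 genes was −5.11 on the log2 scale and −5.80 with the genes at 0 placed at their bound. The genotypes compared therefore also differed in the expression of these genes, and every difference given above lies between libraries that differ in both.

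**Figure D4:**
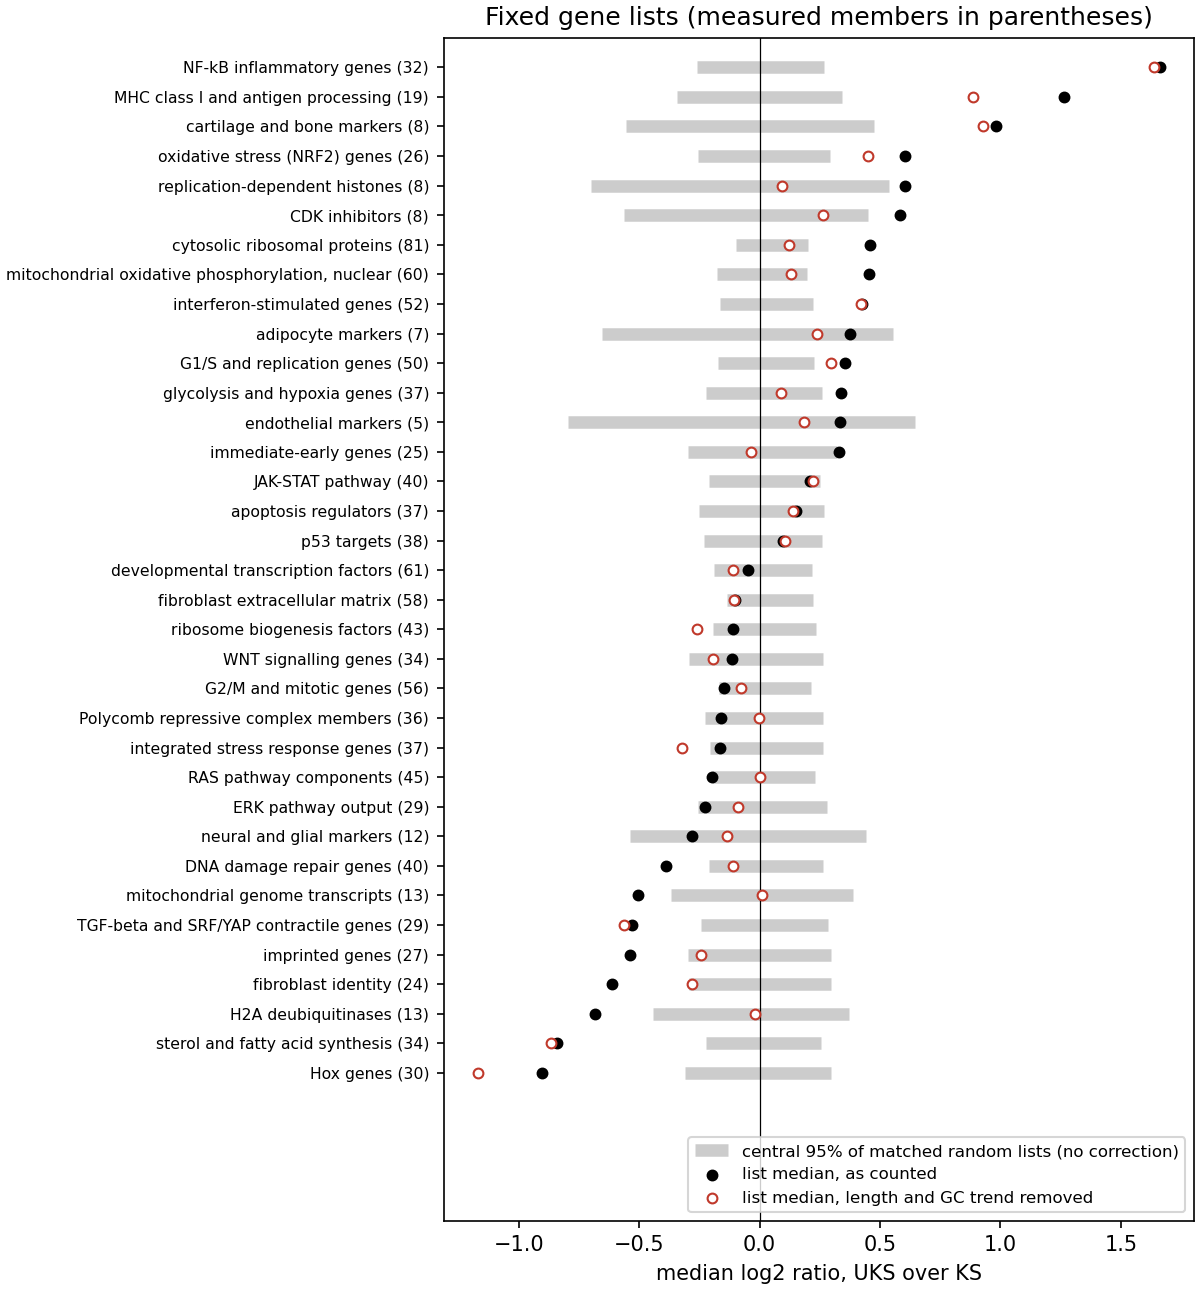
Median log2 ratio of UKS over KS (x axis) of each ranked gene list except the sex-linked one, as counted (filled) and with the trend with length and GC content removed (open), against the central 95% of 10000 matched random lists (grey, as counted). NF-kB and MHC class I lists lie farthest above the grey bars and sterol synthesis and Hox lists farthest below.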

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

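The trend removal and the omission of genes on X and Y were alternatives chosen after seeing the data. Under CPM on library totals, median-of-ratios scaling, a pseudocount of 0.1, no level minimum, a minimum of 5 CPM, protein-coding genes alone and genes on X and Y left out, between 528 and 965 genes were at least 2-fold higher and between 1097 and 1667 at least 2-fold lower, within 1.5 times the 756 and 1396 reported. A pseudocount of 5 gave 412 higher and 836 lower, which follows from its shrinking of low genes. A threshold of 1.5-fold gave 2001 and 2745 genes and one of 4-fold 190 and 206. With the length and GC trend removed 643 genes were lower, the Usp16 log2 ratio was −0.88, and signs reversed for Xiap (0.048) and for the medians of the immediate-early genes (−0.034), the mitochondrial genome transcripts (0.011) and the RAS pathway components (0.0011); Asxl3 (0.018), Brcc3 (0.28) and Myl4 (−0.22), not past 2-fold on the log2 scale as counted, also turned. The median of the replication-dependent histones was −0.037 with no level minimum, where mostly undetected copies enter the list. With no level minimum the medians of the WNT signalling genes (0.024), the developmental transcription factors (0.024) and the skeletal muscle markers (0.17) also changed sign, and at a minimum of 5 CPM that of the developmental transcription factors (0.24). The medians of all 40 lists kept their sign under both other scalings. The RAS pathway list (percentile 2.45) was inside on a redraw of 2000 random lists with no change of setting (2.78), so its loss cannot be put down to the other settings, except the trend removal (percentile 44.7). Inside in some settings, on 2000 lists each, were the immediate-early genes (pseudocount 0.1, minimum of 5 CPM), whose reported percentile of 97.9 also lay near the edge, the H2A deubiquitinases and histones (no level minimum) and the imprinted genes (protein-coding genes alone). Outside in some settings, though inside as reported, were the integrated stress response genes (no level minimum, minimum of 5 CPM, genes on X and Y left out), the WNT signalling genes (minimum of 5 CPM) and the adipocyte markers (pseudocount 0.1). The trend could account for further lists, and 8 of the 22 lists outside the central 95% were inside once it was removed. Ratios resting on under 10 counts in 1 library are limited by depth, as their intervals show. No paired analysis was possible because each group has 1 library.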

Other observations

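The tests of Y chromosome loss, of mitochondrial transcripts and of the Hox paralog groups, and the trend removal itself, were chosen only after the results were seen. The rules of the other tests were written before those tests were run, but after the patterns they address had been seen.

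The Hox genes divided by paralog group, which runs from the head end of the body axis (group 1) toward the tail. All 17 measured genes of groups 6 to 11 were lower in UKS, with a median log2 ratio of −1.12 and a range from −3.14 to −0.07. Of the 13 measured genes of groups 1 to 5, 8 were above 0 and 5 below, with a median of 0.14. Hoxa2 (101 and 215 counts, log2 1.08) and Hoxb2 (205 and 430 counts, 1.15) were the 2 genes at least 2-fold higher, both named after their values were seen and both within 2-fold with the trend removed (0.93 and 0.70). All 6 Hoxc genes were lower, including Hoxc4 and Hoxc5 of the groups nearer the head, with a median of −2.36. Without that cluster 8 of 11 genes of groups 1 to 5 were above 0 and 0 of 13 genes of the later groups were. With the trend in length and GC content removed, 5 of the 13 genes of groups 1 to 5 and 0 of the 17 later ones were above 0, with medians of −0.08 and −1.42. Hox genes of 1 cluster lie side by side and are not independent. Whether the embryos or the parts of them that gave the 2 lines account for this was not tested.

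Xist was counted in UKS and the Y-linked genes in KS, so the genotypes differ in sex-linked expression as well as in Usp16. Loss of the Y chromosome from a male line would leave Xist silent, and the 6998 Xist counts in UKS (Poisson interval 6835 to 7164) argue against it as the whole cause. Lines from embryos of different sex remain a candidate explanation, which Xist in UKS and the Y-linked genes in KS raised. Genes that escape X inactivation would then be higher in UKS than autosomal and other X-linked genes. The 7 such genes lay −0.14 from the autosomal median (bootstrap interval −0.55 to 0.24), and 0.36 (−0.21 to 0.59) with the trend removed. Their median was −0.10 against −0.30 for 412 other X-linked genes, and 0.37 against −0.08 with the trend removed, without an interval. The escape gene test is undecided, because both intervals from the autosomal median include equal levels. The labels give no sex, so a mix-up of a line or of a label also stays open and was not tested; Usp16 was lower in UKS (1195 and 459 counts), the direction that the labels call for, but counts per gene from 1 library per genotype do not settle it. Because sex-linked expression and Usp16 genotype go together here, any difference that depends on sex, autosomal or X-linked, cannot be told apart from one that depends on Usp16. Of the genes named above, Agtr2, Dgkk, Pola1, Xiap, Brcc3, Dkc1 and Scml2, all lower in UKS as counted, lie on the X chromosome.

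The ratios followed transcript length and GC content, and a candidate explanation is recovery of RNA in library preparation or sequencing that differed between the libraries. Transcripts of the mitochondrial chromosome, made by another polymerase, would then follow the trend too; their median stood at percentile 52.9 of random lists once it was removed, but their log2 ratios ran from −0.56 to 1.10, so the test is undecided. For Usp16 a log2 ratio of −0.88 (−1.04 to −0.72) was left of −1.16 once the trend was removed. The bound of −0.87 was a fixed share of the uncorrected ratio, by a rule written before this test but after the trend had been seen. The counting interval does not place the Usp16 ratio on either side of this bound. The trend leaves part of the ribosomal protein difference, at percentile 99.8 and a median of 0.12 in place of 0.46, and the respiratory chain genes at percentile 97.7 are too close to the edge of the central 95% to decide. An effect of Usp16 on long or AT-rich genes would look alike and was not tested.

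NF-kB and MHC class I transcripts were higher in UKS together. Length and GC content are argued against as the whole cause, since the lower of the percentiles of both lists was 100 with the trend removed, and reads shared between H2 paralogs are argued against as the whole cause of the MHC list, since its 11 members outside that family had a median of 1.13, at percentile 100. Blood cells in the culture are argued against as the source of the H2-K1 difference by 9 of their genes. Their summed level was 1.10 CPM in KS and 2.87 CPM in UKS, a difference of 0.248% of the 713 CPM by which H2-K1 was higher. Coro1a alone made up 0.909 CPM of the sum in KS and 2.53 CPM in UKS. The sum was set against H2-K1 only, so blood cells as a source of the NF-kB transcripts were not tested. Cd14, a blood cell list member outside these 9, stood at 18.8 CPM in KS and 62.3 CPM in UKS. Not every kind of blood cell makes all 9, so their sum does not cover each kind. Of the 9, Ptprc stood at 0.0758 CPM in KS and 0.0428 CPM in UKS. A response of the cells to the loss of Usp16 may underlie the pattern, as a hypothesis, but with 1 line per genotype it cannot be told apart from another difference between the lines, such as sex or culture state.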
